A study of Copadichromis virginalis x Mchenga conophoros with 6 samples.

How the data were processed

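Whole-brain RNA of male F1 hybrids of Copadichromis virginalis and Mchenga conophoros was extracted with Trizol and made into Illumina libraries, per the labels' protocols. The authors deposited, for each of 6 libraries, a table of read counts per gene on the C. virginalis allele and on the M. conophoros allele, with the log2 ratio of the 2, per the file headers. STAR 2.4 is named in the submitters' processing notes. The genome build, the annotation, the set of informative sites and the allele counter are not given in the sources used here, and neither is strand. The deposited counts are whole numbers without normalization, and the deposited log2 ratio equalled log2 of the count ratio to within 5.33e-15. A table of the whole series held the 6848 genes listed in all 6 libraries, and its 12 count columns were the same as the library tables, which were used.

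Each library table listed only genes with at least 6 counts on both alleles, and the castle building tables only genes with a total of at least 21. A gene missing from a table is therefore not a count of 0. A gene almost wholly on a single allele appears only where the other allele reached 6 counts, as for COX1. Before the data were examined, missing genes had been set to count as 0 and castle building as 2 animals. Both choices were changed after the files were seen. The main fits used the genes listed in all 6 tables, and the rounded mean of the 2 castle building libraries was 1 sample, because they differed by less than sampling noise. The design as first fixed was computed as an alternative.

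Counts per library were 3294397 and 2243289 for pit digging, 2187643 and 2191037 for castle building and 2155680 and 2275100 for isolation. Genes entered a test if the mean total of both alleles over the 5 samples was at least 20, which left 6844. Of the genes listed in all tables, 3922 had a symbol and 2926 an LOC identifier.

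Allelic counts were fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest) with an intercept per animal and an allele coefficient per paradigm, both alleles of an animal sharing the library size of their sum. The mean of the 3 coefficients, each coefficient and their differences were tested, with 2 residual degrees of freedom. Sums of both alleles were fitted with TMM normalization and paradigm as the factor, also with 2 residual degrees of freedom. The biological coefficient of variation was 10.8% for the allelic fit and 34.1% for the sums. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 value was its size divided by the square root of the F statistic. CPM are sums of both alleles scaled to a common library size with TMM factors. Exact Clopper-Pearson 95% intervals, which cover counting error only, were computed for the shares of whole libraries and of mitochondrial genes. Other shares of genes in the single castle building sample carry no interval.

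Named genes had a symbol, passed the threshold, had a mean total of at least 50 and the same direction in every sample involved (for differences, no overlap between groups), and, for allelic tests, at least 3 counts over all samples on the lower allele. The 12 with the largest fold in each direction were taken. Where fewer than 10 genes passed, the 10 with the smallest p were given as values. Some genes that the rule takes are not reported here. From each list, up to 4 members with the smallest p were taken. Genes with copies in the fish genome can share reads, which the allele counting could split.

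Of 20 gene lists, 15 had 5 or more tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry, adjusted over the lists of each contrast. The lists for monoamine signalling (1 member), microglia and leukocytes (3), erythrocytes (2), pituitary (3) and retina and pineal (0) were too small. Alternatives were DESeq2 1.42.0, TMM between alleles, other filters, sums from 1 allele, a replicate block, missing genes as 0, other treatments of castle building and each library left out.

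The procedure was tested on simulated data: counts for the 6844 genes with 200 changed. Each simulated gene had the spread that the fitted trend gave for its count level. Differences in spread between genes of like level were not simulated, so recovery in the real data can be lower. Over all animals, 59.7% of 1.5-fold and 100% of 2-fold and 4-fold allelic differences were recovered, with 15 false calls. For the allelic ratio between pit digging and castle building 7.81% of 2-fold and 80.3% of 4-fold changes were recovered, and for sums between these groups 25% of 4-fold changes. Adding up both alleles per gene gives no more than the reads over informative sites, so a change in the number of such sites between libraries would appear as a change in the sum.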

Results

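Whole brains of male F1 hybrids between 2 Lake Malawi cichlids were profiled by RNA-seq, and the reads of each gene were divided between the 2 parental alleles. Copadichromis virginalis males dig pits as spawning bowers, whereas Mchenga conophoros males build sand castles, and an F1 hybrid carries 1 copy of each parental genome in the same cells. The animals had been taken through a paradigm for pit digging (2 libraries), castle building (2 libraries) or social isolation (2 libraries). Each library held between 2155680 (isolated replicate 1) and 3294397 (pit digging replicate 1) allele-assigned counts, over 8829 to 11716 listed genes. The values are counts of reads that carried allele-informative sites, so a sum of both alleles follows expression only as far as such reads do. No genome or annotation was used here, so genes are given by the symbols in the files, without positions.

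The 2 castle building libraries differed by less than the sampling noise and were counted as 1 sample, their mean. Their summed counts gave a chi-square per degree of freedom of 0.495, against 27.3 for the pit digging pair and 20.4 for the isolated pair, and 25.6% of the genes listed in both had identical counts on both alleles. Castle building therefore has n = 1 throughout, with no replicate check of its own, and its comparisons assume that the lone sample varies like the other groups. The labels do not say whether the replicates came from separate animals or broods, so p-values measure only the spread between these samples. Of 13212 genes listed in any library, 6848 were listed in all 6 and 6844 of these were tested.

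**Figure D1:**
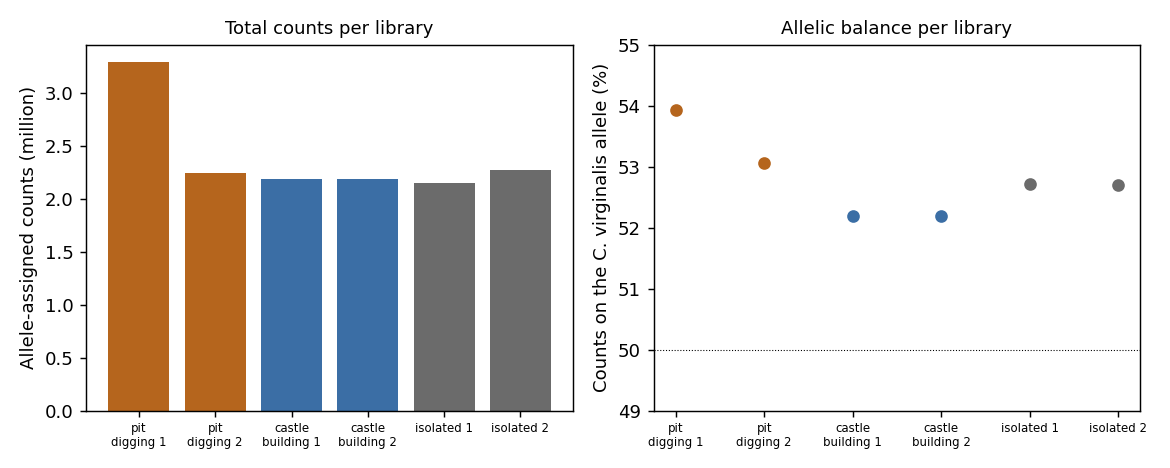
Left, allele-assigned counts per library; right, the percentage of these counts on the C. virginalis allele, on an axis that starts above 0, with a dotted line at 50. All 6 libraries lie above 50%, from 52.2% in castle building to 53.9% in pit digging replicate 1.

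The C. virginalis allele held slightly more than its equal share of the counts in every library. The share was 53.5% ± 0.610 in pit digging (SD, n = 2), 52.7% ± 0.0125 in isolated animals (SD, n = 2) and 52.2% in the castle building sample, with a mean of 52.9% ± 0.641 over the 5 samples (SD, n = 5). Counting error was smaller than the differences between paradigms: the exact 95% binomial interval for pit digging replicate 1 ran from 53.87 to 53.98%, which covers counting error only. It was not smaller than the gap between the isolated libraries. The interval of isolated replicate 1 (52.65 to 52.78%) held the share of replicate 2 (52.70%). Pit digging exceeded isolation by 0.785 percentage points, with p = 0.333 in a two-sided exact permutation test, the smallest value that 2 against 2 samples allow.

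The first question was which genes the 2 alleles express unequally in the hybrid brain. Over all animals, 562 of 6844 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 530 of them higher on the C. virginalis allele and 32 higher on the M. conophoros allele. The median fold was 1.60 for the former and 1.54 for the latter. The test averaged the 3 paradigms, so the single castle building sample weighed as much as both samples of another paradigm. Shares below are means over the 5 samples with equal weight, and their SD is not the spread tested. The direction held in all 5 samples for 420 of the 530 and 23 of the 32, and 137 and 4 of them exceeded a 2-fold difference. The gene dazap2, which encodes a small proline-rich protein that binds DAZ, had 92.6% ± 3.36 of its counts on the C. virginalis allele (SD, n = 5; log2 ratio 3.85 ± 0.16 SE, adjusted p = 1.41e-05). For tmbim4, a Golgi membrane protein, the share was 85.8% ± 11.2, and for the Golgi tethering subunit cog8 84.6% ± 6.89. Shares between 76.8 and 82.5% were found for the endophilin gene sh3glb2, the serine incorporator serinc1, the syndecan sdc3, the adenylate kinase ak1, the astrocyte membrane protein mlc1, the calsyntenin clstn1, the chromatin remodelling subunit dpf2 and tpt1. The translation-associated gene tpt1 had 76.8% ± 10.4.

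On the M. conophoros side, the mitochondrially encoded cytochrome oxidase subunit COX1 stood at 0.217% ± 0.0322 C. virginalis counts (SD, n = 5; log2 ratio -8.80 ± 0.07 SE, adjusted p = 1.06e-09). If the mitochondria came from a single parent, a candidate taken up below, COX1 has no other allele to compare. The cilium-associated gene tbc1d32 had 23.7% ± 10.4 on the C. virginalis allele (log2 ratio -1.75 ± 0.17 SE). Smaller differences towards M. conophoros were found for arl6ip1, an endoplasmic reticulum shaping protein (35.1% ± 5.09), the exocyst subunit exoc4 (36.8% ± 3.31), gemin8 of the spliceosome assembly complex (37.6% ± 2.87) and the integrin itgb1 (37.9% ± 6.505). The co-chaperone aip (39.4% ± 3.65), the dense-core vesicle protein ptprn (41.8% ± 8.65), jkamp (41.9% ± 1.43), the transcription factor sox5 (42.7% ± 6.58), the perinodal matrix protein hapln2 (43.2% ± 7.59) and the sulfotransferase sult6b1 (43.7% ± 5.62) completed the named genes. Fewer genes passed without isolated replicate 1 (342) or replicate 2 (293), or with DESeq2 (263).

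**Figure D2:**
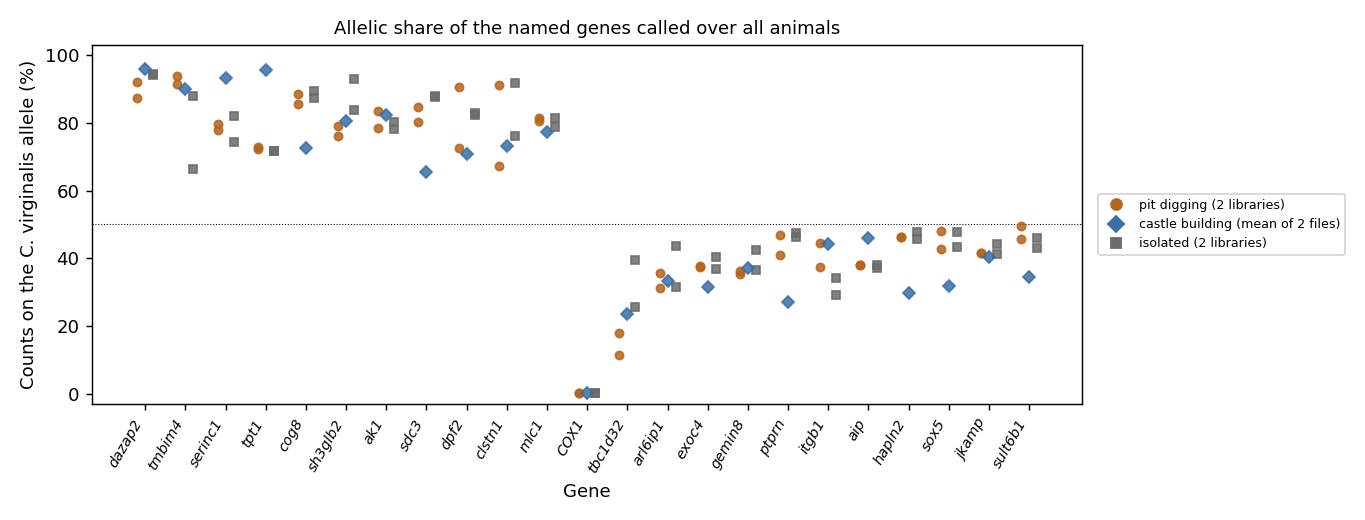
Percentage of a gene's counts on the C. virginalis allele (vertical axis) in each of the 5 samples, for 23 named genes called over all animals; the dotted line marks 50%. The 11 genes on the left lie above 50% in every sample, and the 12 on the right lie below it, with COX1 near 0.

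Several groups of brain genes held members with unequal alleles. Of 41 synaptic scaffold, adhesion and plasticity genes, 8 were higher on the C. virginalis allele, 0 were lower and 33 did not pass (11 passed adjusted over the list alone, 10 higher and 1 lower). They included the calcineurin subunits ppp3r1 (74.2% ± 4.29, SD, n = 5; log2 ratio 1.63 ± 0.07 SE) and ppp3ca (59.8% ± 5.23) and the calmodulins calm3 (71.2% ± 11.7) and calm2 (66.0% ± 2.12). Of 14 genes for GABA synthesis, transport and receptors, 5 were higher on the C. virginalis allele and 9 did not pass (6 higher and 1 lower adjusted over the list alone). Among them were the receptor gabbr2 (55.3% ± 3.06), the synthetic enzyme gad2 (53.2% ± 6.76) and the GABA transaminase abat (55.4% ± 15.2). The mean share of gad2 lay near the 52.9% of all counts. Without the castle building sample abat no longer passed, with a log2 ratio of -0.05. Of the genes taken by name or list that passed over all animals, 39 kept their call without that sample. A further 7 lost it and 2, abat among them, reversed direction. Of 8 cell division and neurogenesis genes, the neuronal RNA-binding genes elavl3 (60.6% ± 3.44) and elavl4 (61.7% ± 4.43) were higher on the C. virginalis allele (5 higher adjusted over the list alone). Of 6 radial glia, astroglia and ependyma genes 3 were, namely the glutamate transporter slc1a2 (60.1% ± 7.38), ndrg2 (57.1% ± 7.62) and pltp (60.5% ± 5.99), also 3 adjusted over the list alone.

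In the remaining lists, the granins chgb (71.7% ± 17.6) and chga (56.9% ± 5.04) were 2 of 13 neuropeptide genes that passed (4 higher and 1 lower adjusted over the list alone). Of 21 voltage-gated channel genes, the potassium channel kcnc1 (66.9% ± 4.73) and the sodium channel subunit scn2b (57.6% ± 5.76) were higher on the C. virginalis allele, and the calcium channel subunit cacnb2 (41.0% ± 4.86) was lower, with the same counts adjusted over the list alone. Single genes passed among 8 glutamate receptors (gria2, 64.1% ± 11.7), 10 oligodendrocyte and myelin genes (mpz, 55.2% ± 4.70), 7 oxidative phosphorylation genes (ndufb3, 57.9% ± 1.51) and 14 cytosolic ribosomal proteins (rpl12, 56.1% ± 2.12), each higher on the C. virginalis allele. Among 11 heat shock genes the chaperone hsp90b1 was lower on that allele (47.0% ± 10.3), and it did not pass without the castle building sample, where its log2 ratio was 0.09. The counts of these 5 lists were the same adjusted over the list alone. No gene passed among 7 immediate early, 8 vascular and meningeal or 10 circadian clock genes, over all genes or adjusted over the list alone. The same held over all genes for 7 steroid and thyroid signalling genes, of which 2 were higher adjusted over the list alone. None of the 15 lists moved as a set by camera (smallest adjusted p = 0.14).

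Each paradigm was then tested on its own within the same fit. In pit digging 451 genes passed (edgeR), 433 higher on the C. virginalis allele and 18 on the M. conophoros allele. In isolation 301 passed (285 and 16), and in the castle building sample 117 (109 and 8). Pit digging and isolation, which share no libraries, had 209 genes called towards C. virginalis in both, against 18.0 if the lists were independent. Towards M. conophoros 7 were shared against 0.0421, with 0 in opposite directions. Pit digging and castle building had 73 and 4 in both, against 6.90 and 0.0210. Castle building and isolation had 60 and 3, against 4.54 and 0.0187, with 1 gene in opposite directions in each of these pairs. All lists came from the same fit and share each gene's spread estimate, its depth and any mapping bias. Overlap above the independent value could therefore arise in advance, and it is no test of replication. Of the pit digging calls 74.7% had the same sign in castle building and 94.5% in isolation. In pit digging, the granin chgb had 89.9% ± 4.64 of its counts on the C. virginalis allele (SD, n = 2), the transcriptional regulator id2 89.1% ± 2.92 and the adhesion receptor adgrb1 88.2% ± 10.7. In isolation, id2 stood at 88.2% ± 0.463, the antigen-presentation chain cd74 at 92.6% ± 0.407 and the amyloid precursor gene app at 80.8% ± 3.87, while the autophagy gene gabarap stood at 24.7% ± 8.47. In castle building the share was 98.0% for the RNA-transport gene stau1, 92.0% for itfg1 and 86.4% for mien1. Without pit digging replicate 1 the pit digging count was 178. Without isolated replicate 1 or 2, the isolated count was 69 or 80 and the castle building count 51 or 48. DESeq2 gave 176 genes for pit digging, 62 for castle building and 135 for isolation.

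The contrast between the 2 bower behaviours asked whether the allelic ratio itself depends on behaviour. It differed between pit digging and castle building for 11 genes (edgeR interaction), 4 with a higher C. virginalis share in pit digging and 7 with a lower one. The Na,K-ATPase family member atp1b4 had 74.8% ± 1.42 C. virginalis counts in pit digging (SD, n = 2) and 9.03% in castle building, a difference of 4.90 ± 0.30 (log2, SE; adjusted p = 0.00347). The ubiquitin ligase mgrn1 went from 86.8% ± 4.03 to 40.9% (3.37 ± 0.31, adjusted p = 0.0103). In the other direction, tpt1 had 72.5% ± 0.555 in pit digging and 95.4% in castle building (-2.98 ± 0.21, adjusted p = 0.00474). The RNA helicase ddx5 had 68.3% ± 2.70 and 92.5%, the condensin subunit ncapd2 53.1% ± 10.7 and 88.3%, the ubiquitin ligase adaptor wsb1 48.98% ± 0.826 and 78.5%, and the phosphoprotein-binding adaptor ywhaq 61.9% ± 0.341 and 85.4%. The castle values come from a single sample, and the count was 43 without pit digging replicate 2, with 30 higher and 13 lower in pit digging, 17 without the first castle building file, 7 without isolated replicate 1 or 2, 7 with missing genes as 0 and 20 with TMM between alleles. No list member passed over all genes. Adjusted over the list alone, 4 synaptic genes had a higher and 3 a lower C. virginalis share in pit digging. In the same way 1 glutamate receptor, 1 radial glia gene and 1 heat shock gene had a higher share. A lower one was found for 2 GABA genes and 1 oligodendrocyte and myelin gene.

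Castle building against isolation gave 18 genes (edgeR interaction), 11 with a higher C. virginalis share in castle building and 7 with a lower one. This contrast shares the castle building sample with the one above. The genes tpt1 (71.7% ± 0.134 in isolation, SD, n = 2; difference 3.03 ± 0.21, log2, SE), ncapd2 (53.5% ± 5.87), ddx5 (67.5% ± 0.4998) and ywhaq (63.0% ± 1.79) again had the higher share in castle building, and atp1b4 (67.5% ± 10.6; -4.61 ± 0.34) the lower one. Beyond these, the GABA transaminase abat had 80.9% in castle building and 46.6% ± 3.91 in isolation, the exocyst subunit exoc6 78.4% and 49.5% ± 0.567, and the cadherin cdh13 75.0% and 51.1% ± 0.189. The pit digging share of cdh13, given below, lay near its castle building value, so for this gene the isolated samples stood apart. The neuronal stathmin stmn2 (44.0% against 77.7% ± 3.77) and the secretogranin scg3 (47.8% against 73.3% ± 1.44) had the lower share in castle building. The count fell to 6 and 4 without isolated replicate 1 and 2, rose to 30 and 32 without pit digging replicate 1 and 2, and was 8 with a mean total of at least 100 or with missing genes as 0. Of the 14 GABA genes abat passed over all genes, and 3 had a higher and 1 a lower share adjusted over the list alone. In the same way 1 of 10 oligodendrocyte and myelin genes had a higher share in castle building and 1 of 11 heat shock genes a lower one.

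**Figure D3:**
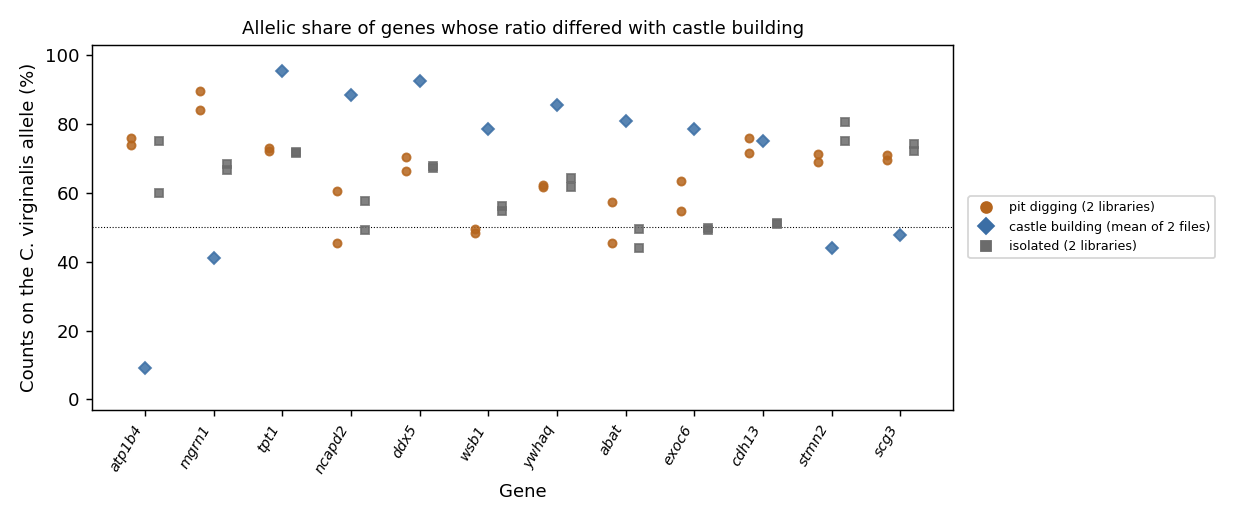
Percentage of a gene's counts on the C. virginalis allele in each of the 5 samples, for the 12 named genes whose allelic ratio differed between castle building and another paradigm; the dotted line marks 50%. In castle building atp1b4 lies at 9.03% and tpt1 at 95.4%, away from the other 4 samples.

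Between pit digging and isolation, no allelic ratio passed (0 genes, edgeR; 387 at an unadjusted p under 0.05; 1 with DESeq2). The gene with the smallest p was cdh13, with 73.8% ± 3.11 C. virginalis counts in pit digging and 51.1% ± 0.189 in isolation (SD, n = 2 each; difference 1.43 ± 0.18, log2, SE, adjusted p = 0.172). The calmodulin calm3 stood at 83.4% ± 1.90 against 61.5% ± 5.99, mgrn1 at 86.8% ± 4.03 against 67.4% ± 1.27, chgb at 89.9% ± 4.64 against 59.3% ± 10.4 and the actin-binding gene lasp1 at 74.9% ± 4.02 against 44.2% ± 2.09. Values for gabarap were 53.6% ± 4.91 and 24.7% ± 8.47, for the RNA-binding gene khdrbs1 63.3% ± 0.839 and 49.8% ± 2.10, for jade2 64.4% ± 2.002 and 51.1% ± 3.16 and for the contactin cntn1 65.5% ± 3.94 and 49.4% ± 1.97. The tubulin gene tubb went the other way, with 48.9% ± 1.61 and 68.8% ± 7.62. The count was 3 without pit digging replicate 1, 12 without replicate 2 and 1 without isolated replicate 1. Adjusted over the list alone, 1 of 14 GABA, 1 of 13 neuropeptide, 1 of 41 synaptic and 1 of 6 radial glia genes had a higher share in pit digging. A lower share was found for 1 of 8 cell division and neurogenesis genes. On simulated data, where genes of like count level had the same spread, this contrast recovered 36.2% of 2-fold and 90.8% of 4-fold changes. Real genes differ in spread, so these percentages do not show that such changes were absent here.

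Summed over both alleles, 321 genes differed between pit digging and castle building (edgeR, TMM), 224 higher in pit digging and 97 higher in castle building. The ribosomal protein gene rpl4 had 693.4 ± 109 TMM-normalised CPM in pit digging (SD, n = 2) and 11.2 in castle building, a log2 difference of 5.95 ± 0.36 (SE; adjusted p = 0.0408). Other genes lower in castle building were chgb (1121 ± 583 against 29.1 CPM), ndrg3 (1510 ± 169 against 59.7), the clathrin adaptor subunit ap2m1 (613 ± 88.0 against 31.1), apc (484 ± 28.2 against 18.9), kiaa0513 (362 ± 12.3 against 12.6) and the splicing factor srsf5 (478 ± 183 against 19.9). The phosphorylase kinase subunit phka2, cotl1, cmip, tmem59l and safb2 had folds of 15.7 to 19.5 in the same direction. Higher in castle building were the synaptic adhesion gene lrfn2 (704 against 44.0 ± 1.80), the glutamate receptor grik3 (96.1 against 11.7 ± 4.60), ncapd2 (713 against 74.1 ± 4.35), the chromatin gene pcgf3 (405 against 37.7 ± 8.10) and the secreted factor fam19a5 (401 against 41.4 ± 0.160). The genes cdk19, mapkap1, mpi, lasp1, plekhg1 and hif1an had folds of 8.01 to 16.3 in that direction.

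Against isolation, 460 genes differed in castle building, 167 higher and 293 lower (edgeR). This contrast again rests on the same castle building sample, whose log2 summed counts correlated across genes with those of the other libraries at 0.650 to 0.693, against 0.834 to 0.888 among the others (genes are not independent replicates). Higher in castle building were the glycosyltransferase mgat3 (387 CPM against 12.5 ± 7.26, SD, n = 2; log2 4.94 ± 0.61 SE, adjusted p = 0.0359), dip2c (566 against 32.2 ± 8.41), the neuronal transcription factor mef2d (818 against 64.2 ± 9.71) and the syntaxin stx1a (152 against 13.5 ± 1.76). The genes lrfn2, ncapd2, cdk19, ppp1r12a, znf385b and grik3 had folds of 10.49 to 22.4. Lower were rpl4 (11.2 against 901.7 ± 17.0), safb2 (15.05 against 501 ± 4.0001), kiaa0513, chgb, tmem59l, ap2m1, cotl1, ndrg3, arl6ip1 (17.5 against 375 ± 62.4), phka2, the adaptor subunit ap1m1 (14.6 against 222 ± 11.3) and cmip. Every castle building file lists only genes with a total of at least 21 counts, so genes still lower there did not enter either comparison. The castle building values of rpl4 (11.2 CPM), ap1m1 (14.6), safb2 (15.05) and arl6ip1 (17.5) lie not far above that floor. So do those of kiaa0513, apc and srsf5 given above and of sstr2 given below. Their folds therefore rest on few counts in a single sample. Neither count held with fewer animals: 0 genes passed in both comparisons without pit digging replicate 1, pit digging replicate 2, isolated replicate 1 or isolated replicate 2, each of which leaves 1 residual degree of freedom. DESeq2 gave 854 and 933 genes.

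**Figure D4:**
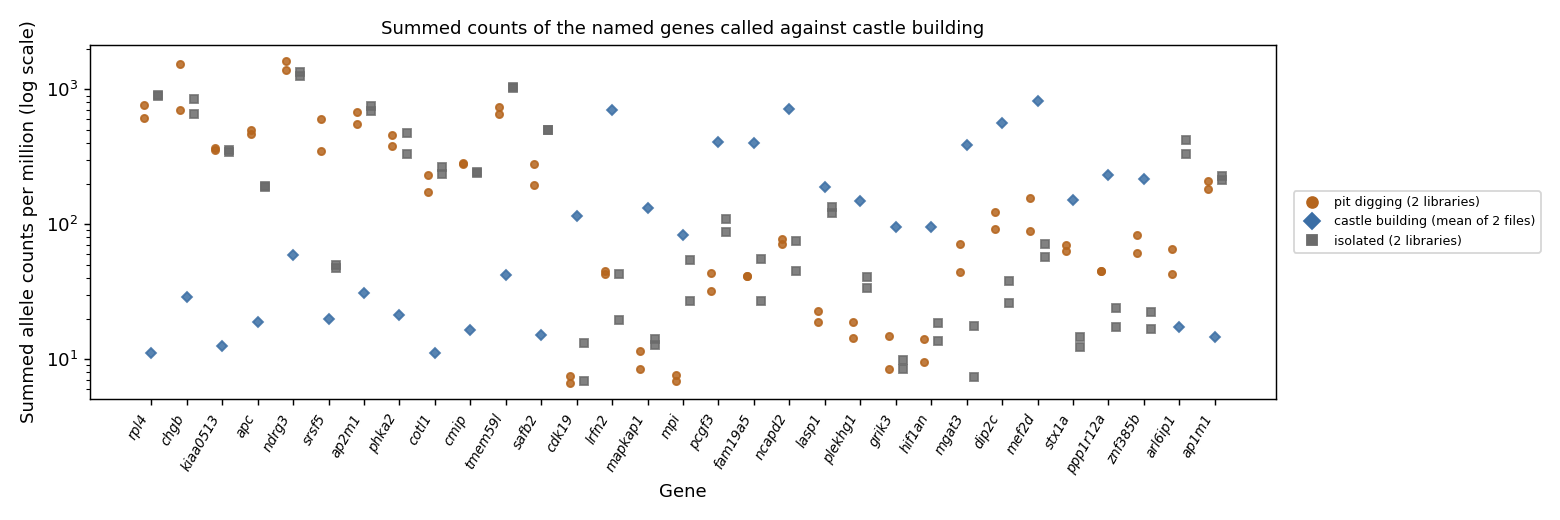
Summed allele counts in CPM (logarithmic axis) in each of the 5 samples, for named genes called between castle building and pit digging or isolation. The castle building value lies above or below every sample of the group it was called against, as for rpl4 at 11.2 and lrfn2 at 704 CPM.

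Among the gene lists, the 14 cytosolic ribosomal proteins were lower in castle building than in pit digging (camera adjusted p = 0.0265) and than in isolation (camera adjusted p = 0.0176). With an estimated correlation these became adjusted p = 0.845 and adjusted p = 0.691. Against isolation 3 members fell (rpl4, rps24 and rpl30; 4 adjusted over the list alone) and 11 did not pass. Against pit digging rpl4 and rps24 passed (5 adjusted over the list alone). The log2 values against isolation ranged from -6.33 for rpl4 to 0.06 for rplp0, which was named after its value was seen, and their SD of 1.69 lay at the 86.6th percentile of 10000 random lists of like expression. That SD rested on rpl4: without it the other 13 genes had an SD of 0.959, at the 12.3th percentile. Of the 14 values 13 were negative. Between pit digging and isolation the SD of the same genes was 0.301, at the 1.27th percentile. No other list passed camera in any of the 10 contrasts.

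**Figure D5:**
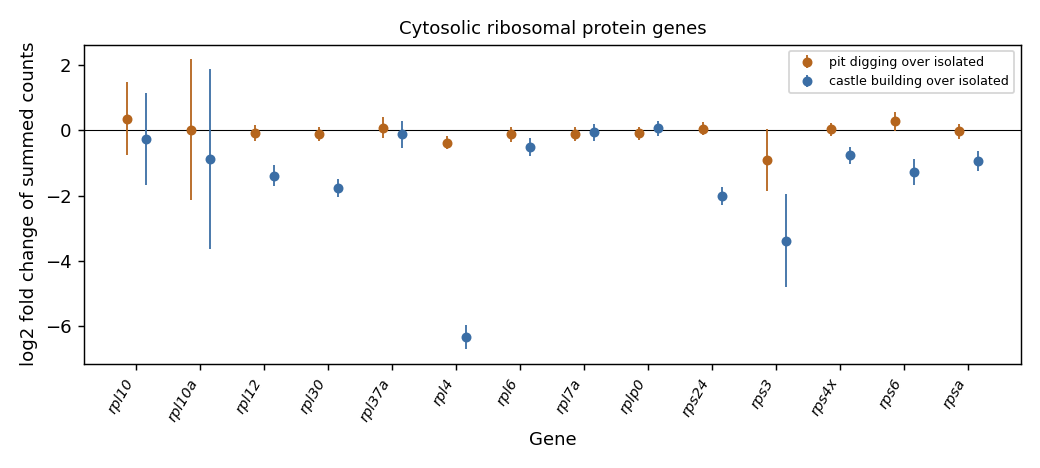
Log2 fold change of summed counts (vertical axis) for 14 cytosolic ribosomal protein genes, in pit digging over isolation and in castle building over isolation; bars are standard errors of the fit. The castle building values spread from -6.33 (rpl4) to 0.06 (rplp0), and the pit digging values from -0.92 (rps3) to 0.36 (rpl10).

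Other list members passed singly against the castle building sample. Of 13 neuropeptide genes, chga (101 CPM in castle building, 806 ± 75.2 in pit digging, 939 ± 59.1 in isolation) and chgb were lower in castle building in both contrasts, and the somatostatin receptor sstr2 (11.7 against 93.2 ± 23.7) against isolation (3 members adjusted over the list alone against isolation; 3 higher and 1 lower in pit digging). Of 10 oligodendrocyte and myelin genes, the myelin protein mpz was lower in castle building (844 CPM) than in pit digging (6528 ± 84.2) and isolation (5441 ± 144), the 1 member that passed, also adjusted over the list alone. Of 8 glutamate receptors, 2, among them grik3, were higher in castle building in both contrasts, also adjusted over the list alone. The GABA receptor subunit gabra5 was lower in castle building (120 CPM) than in pit digging (449 ± 69.0) and isolation (729 ± 45.2), and gabarap was higher than in isolation (104 against 34.7 ± 2.90; of 14 GABA genes, 3 higher and 2 lower in pit digging than in castle building, and 1 higher and 4 lower in castle building than in isolation, adjusted over the list alone). Of 21 channel genes, kcnc1 was lower (37.9 against 338 ± 10.8 and 352 ± 1.38) and cacna2d4 higher (322 against 78.7 ± 7.45 and 51.3 ± 1.88) in both, and cacnb2 higher than in isolation (3 higher and 1 lower adjusted over the list alone). Of 41 synaptic genes, stx1a and shank1 (533 against 114 ± 0.396) were among 3 higher than in isolation, and syn2 (231 against 1396 ± 69.7) and calm3 among 3 lower (5 and 4 adjusted over the list alone); against pit digging syn2 was the 1 member that passed, also adjusted over the list alone. Of 8 vascular and meningeal genes, the retinol carrier rbp4 was lower than in isolation (33.5 against 320 ± 124), also adjusted over the list alone, where 1 member was also lower than in pit digging. The mineralocorticoid receptor nr3c2 was higher than in isolation (282 against 52.1 ± 4.43; 2 of 7 steroid and thyroid genes in each contrast adjusted over the list alone). The respiratory chain genes ndufb3 (49.5 against 189 ± 1.68) and atp5e (47.1 against 190 ± 34.4) were lower than in isolation (3 of 7 adjusted over the list alone; against pit digging 2 were lower and 1 higher in castle building). No immediate early, neurogenesis, radial glia, clock or heat shock gene passed over all genes in either contrast. Adjusted over the list alone, 2 of 11 heat shock genes were lower in castle building than in pit digging and 3 than in isolation, and 1 of 6 radial glia and 1 of 10 clock genes were lower than in isolation.

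Between pit digging and isolation, no summed count passed (0 genes, edgeR; 676 at an unadjusted p under 0.05), while DESeq2 called 128. The gene with the smallest p, the complement-related membrane protein sez6l2, had 464 ± 25.6 CPM in pit digging and 14.6 ± 3.56 in isolation (SD, n = 2 each; log2 4.98 ± 0.30 SE, adjusted p = 0.162). Values were higher in pit digging for gabarap (308 ± 25.3 against 34.7 ± 2.90), the RNA helicase ddx31 (366 ± 36.3 against 64.2 ± 9.66), the co-chaperone st13 (275 ± 25.8 against 63.3 ± 4.68), srsf5 (478 ± 183 against 48.7 ± 1.75) and the phosphatase cdc14b (75.4 ± 4.24 against 7.92 ± 2.19). They were lower for the mitochondrial import gene tomm6 (24.1 ± 1.63 against 168 ± 11.4), the metalloproteinase inhibitor timp4 (43.1 ± 3.04 against 223 ± 13.5), lasp1 (20.9 ± 2.82 against 127.6 ± 9.31) and the respiratory chain gene ndufa6 (14.5 ± 2.14 against 107 ± 7.56). Among list members, shank1 had 386 ± 47.4 and 114 ± 0.396, the receptor gria2 1009 ± 80.2 and 444 ± 43.0, and the prohormone convertase pcsk1 106 ± 14.6 and 298 ± 24.0. Adjusted over the list alone, 1 of 8 glutamate receptors, 3 of 14 GABA genes, 1 of 13 neuropeptide genes, 3 of 41 synaptic genes and 1 of 7 oxidative phosphorylation genes passed. Immediate early genes, which respond to neuronal activity, gave 0 of 7 calls; sgk1 had 210 ± 35.4 and 74.2 ± 32.8 CPM and npas4 94.5 ± 58.4 and 31.3 ± 33.9. On simulated data, again without differences in spread between genes of like level, this contrast recovered 1.43% of 2-fold and 41.9% of 4-fold changes.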

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

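All tests of explanations below were chosen after the results they bear on had been seen.

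Differences in allelic ratio between paradigms, by the interaction test, marked 17 gene results. For pit digging minus castle building the log2 differences were 4.90 for atp1b4, 3.37 for mgrn1, -2.98 for tpt1, -2.70 for ncapd2, -2.49 for ddx5, -1.93 for wsb1 and -1.85 for ywhaq. For castle building minus isolation they were 3.03 for tpt1, 2.74 for ncapd2, 2.55 for ddx5, 2.27 for abat, 1.89 for exoc6, 1.78 for ywhaq, 1.52 for cdh13, -4.61 for atp1b4, -2.16 for stmn2 and -1.58 for scg3. Both sets rest on the single castle building sample.

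The castle building sample stood apart from the other 4 libraries in summed counts. Its correlations across genes with them were 0.650 to 0.693, against 0.834 to 0.888 among the others. Depth is argued against: 3 samples had fewer counts on the tested genes (1901885 to 2006713) than castle building (2015063), and the lowest correlation among them was 0.834, above the highest with castle building of 0.693. Gene-by-gene differences in which sites were counted stay open. The spread of ribosomal protein genes, usually made in step, lay at the 86.6th percentile of random lists between castle building and isolation. Without rpl4 it lay at the 12.3th. Such differences would give mixed signs if the genes varied independently, and 13 of 14 were lower in castle building. The members had an estimated correlation of 0.428 in this contrast, so the count of signs cannot decide. Castle building behaviour cannot be told apart from the individual library or its processing, because it is represented by 1 sample. Its libraries listed no gene with a total under 21, whereas the lowest total was 12 in each of the others. Of 8304 genes listed in all 4 other libraries, 1334 were listed in neither castle building library. The cause of this difference in listing was not tested.

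Most allelic calls were higher on the C. virginalis allele, 530 of 562. A uniform shift towards that allele is argued against as the whole cause, because 88.0% of the calls still lay on that side with TMM between alleles. Genes without a symbol, which could include copies of other genes, are not the whole cause either: of calls with a symbol 93.8% lay on that side. Mapping bias gene by gene stays open, because 420 of the 530 kept their side in all 5 samples, as both bias and a true allelic difference would give. A true difference between the parental alleles stays open and was not tested separately.

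Mitochondrial transcripts, of which COX1 alone was listed in all libraries and tested, carried a signal that the comparisons did not use. Over 6 mitochondrial genes and 21 values, the share on the M. conophoros allele was 97.8 to 99.9%, lowest for ND4 in pit digging replicate 2 at 97.8%. A candidate explanation is that the mitochondria came from an M. conophoros mother; a transcript under 95% would have counted against it, but that bound was set on these same values, so the lowest of 97.8% is no test of it. The labels write the cross with C. virginalis first, an order often used for the mother, which would go against this explanation, but they do not say which parent was the mother. A fixed assignment error of mitochondrial sites was not tested.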

How the results depend on the processing

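The settings that treat castle building as 2 animals, leave it out, use the design as first fixed, or count missing genes as 0 in the sums and lists, and the left-out libraries for lists and balance, were chosen after seeing the data. Counts below are genes passing, in the order all animals, pit digging, castle building and isolation for allelic expression. Where a count moved, the cause was not tested unless stated. With castle building as 2 animals the allelic counts were 1093, 709 and 619 for the first 3. Counting near-identical libraries as replicates lowers the estimated spread. Of the castle building calls 71.9% were then higher on the C. virginalis allele, against 93.2% in the main fit. The design as first fixed gave 413 for castle building, with 77.5% higher on that allele. DESeq2 gave 263, 176, 62 and 135. Without each library the ranges were 293 to 618, 178 to 449, 48 to 151 and 69 to 382.

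For the allelic ratio of pit digging minus castle building (11 genes), the count was 7 with missing genes as 0, 20 with TMM between alleles, 31 with the replicate block (19 higher and 12 lower in pit digging, against 4 and 7), 273 with castle building as 2 animals and 70 with the design as first fixed, and 7 to 43 without each library; 8 remained with a mean total of at least 100, all among the 11. DESeq2 split its 14 into 7 and 7. For castle building minus isolation (18 genes) it was 8 with a mean total of at least 100, 8 with missing genes as 0, 209 with castle building as 2 animals, 30 with the design as first fixed and 4 to 32 without each library. For pit digging minus isolation (0 genes) it was 3 with the replicate block, 1 with DESeq2 and 0 to 12 without each library.

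For sums of pit digging against castle building (321 genes), the count was 0 with the replicate block, 1428 with missing genes as 0, 2648 with castle building as 2 animals, 3762 with the design as first fixed, 854 with DESeq2 and 0 to 331 without each library. For castle building against isolation (460 genes) it was 0 with the replicate block, 1454 with missing genes as 0, 2734 with castle building as 2 animals, 3794 with the design as first fixed, 933 with DESeq2 and 0 to 469 without each library. The block and each left-out pit digging or isolated library leave 1 residual degree of freedom. Directions held, which is no test: the castle building sample is shared. Missing genes as 0 moved the median of all genes to 0.25 and -0.23 (log2) in these contrasts. The split of the calls moved too. Of those against castle building, 69.8% were higher in pit digging in the main fit, 85.6% with missing genes as 0 and 58.0% with castle building as 2 animals. Against isolation, 36.3% were higher in castle building in the main fit, and 15.7% and 43.2% with these settings. For pit digging against isolation (0 genes) it was 169 with castle building as 2 animals, 302 with the design as first fixed, 128 with DESeq2 and 0 without each library in turn.

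The labels do not say what the replicate numbers mark. Same-numbered pit digging and isolated samples deviated with correlations across genes of -0.0952 for sums and -0.0323 for allelic ratios. These values show no evident pairing but cannot exclude it, because each group gives a single difference between replicates. The block gave 599, 494, 125 and 354 allelic genes and 0 for sums of pit digging against isolation. The 2 list calls became 0 with an estimated correlation, 0 with fry's directional test (its test for change in either direction gave the ribosomal list adjusted p = 0.0129 and 0.0163, with 11 and 10 of 15 lists passing), 1 with missing genes as 0, 1 with the design as first fixed, 3 with the replicate block and 1 to 3 without each library; with no castle building library their contrasts could not be run. The mean C. virginalis share of 52.9% was 52.7 to 53.0% without each library and 53.0 to 53.1% under the other settings. Of 3440 alternative values for 231 named results, 2726 were unchanged in call, 656 lost the call, 56 gained it and 2 reversed. A change of direction was counted only where the gene passed in the main fit or in the alternative. The reversed ones were abat at -0.0486 and hsp90b1 at 0.0876 over all animals with no castle building library. The simulated data had no differences in spread between genes of like level. There, 2-fold changes of the allelic ratio were recovered in 7.81% of cases between pit digging and castle building. Between pit digging and isolation it was 36.2%. What depth limits was not tested separately.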
